A study of Mus musculus with 2 samples.

How the data were processed

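Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the intestine of mice at postnatal day 0. Per the labels, there were 2 biological replicates, each labelled as a pool of male and female pups of a C57BL/6N background. Replicate 1 was made from 15 mice, and the number of mice in replicate 2 is not given in the sources used here. The labels number these as separate biological replicates with separate tissue records but give both the same donor identifier. They do not say whether litters were separate, so agreement between replicates may in part be technical. Each replicate combined 2 technical replicates, and libraries were size-selected at 300 to 500 bp. The tissue was whole intestine, so every value is an average over epithelium, muscle, connective tissue, nerve, vessel and blood cells.

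The peak lists, on the mm10 assembly (GRCm38), were a list called on each replicate, a list called on the pooled reads of both replicates, and a replicated list. Per the file headers, the replicated list was derived from the pooled list and both replicates' lists. All 48060 of its rows were rows of the pooled list when this was tested, so its values are those of the pooled call. Of the pooled peaks on chromosomes 1 to 19, X and Y, 39706 overlapped a peak of each replicate by at least 50% of either peak, and all 39706 were in the replicated list. A further 8346 replicated peaks were not matched in both replicates under that rule, and the authors' own rule is not given in the sources used here.

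Per the file headers, the lists are in narrowPeak format. In each deposited list, the fold of a peak is the authors' ratio of ChIP signal over control. The strength of the call is deposited as −log10 of the p-value and −log10 of the q-value. The fold is used here to describe, rank or filter peaks within a list, and in the closing section to compare X-linked with autosomal promoter peaks of the replicated list. The aligner, the peak caller, the calling threshold, the control library's treatment and the read depth are not given in the sources used here. Read depth sets how many weak peaks a caller finds, so a missing peak means that none was called at an unknown depth. The lists differed in length, which makes ranks and counts of weak peaks incomparable between replicates unless the lists are brought to equal length. Per-peak values of the pooled call carry no replicate error. Where a replicate's own list gave a named peak a fold that differed from the pooled one by more than 1.5 times, the values in both replicates' lists are given beside it.

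Peaks were compared and annotated with bedtools 2.31.1, and statistics were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Peaks on unplaced sequences were left out of the comparisons. A peak counted as found in the other replicate when an overlap covered at least 50% of either peak. The share found was compared with 100 random placements of the same peaks on the same chromosomes, leaving out runs of 100 or more undetermined bases. This one-sided test cannot give a p under 0.0099.

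Genes were the 21938 protein-coding genes of GENCODE release M21, with 93513 transcript starts. A promoter was the 1 kb on either side of any of these starts. The promoter CpG observed/expected ratio was measured only in the 500 bp on either side of each gene's outermost 5′ end. For a gene marked at another start, it is therefore not the ratio of the marked promoter. A peak lay at a promoter when any of its bases overlapped one. Other peaks were assigned by their centre to exon, intron or intergenic sequence, in that order. Distal peaks were replicated peaks over 1 kb from every protein-coding transcript start, and each gene was given the number of them within 50 kb of its starts. For stitched distal regions, replicated peaks over 2.5 kb from every protein-coding start were joined when they lay within 12.5 kb of each other. The regions were ranked by the bases that peaks covered.

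The design, the tests, 28 gene lists with 441 members and the alternative settings were fixed before the data were examined. All 441 members were found in the annotation, 1 of them under an older symbol. The share of a list's members with a promoter peak was compared with all other protein-coding genes by a two-sided Fisher's exact test. The median number of distal peaks was compared with 10000 random lists of the same size, two-sided, where the smallest possible p is 0.0002. Genes of random lists were drawn with replacement from all protein-coding genes, or from matched ones where stated. Tests against random lists or random placements are called permutation tests below for short. Members with a promoter peak in 1 replicate only were compared by a two-sided exact McNemar test, which compares these 2 libraries. Each family of 28 tests was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Genes are not replicates, and neighbouring genes can share peaks, so p-values over genes describe this pooled material. Intervals on shares are 95% Wilson intervals and cover counting error only.

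Named genes followed a rule. In each list these are the 2 members with the highest authors' fold in a replicated promoter peak, and any member may be named as having no peak. The genes nearest to the 10 replicated peaks of highest fold and to the 10 leading stitched regions were also named. In lists that differed between replicates, the members that differed were to be named. Other genes are said to have been chosen after their values were seen. The alternatives covered the overlap rule, a q of 0.01 or less, lists of equal length, promoter windows of 500 and 2500 bp, and the outermost 5′ end only. They also covered each replicate's own list, distal windows of 20 and 100 kb, matched background genes, and the joining distance, promoter exclusion and ranking of stitched regions.

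The procedures were tested on simulated data. All 8000 simulated shared peaks were found, and 0.942% of unrelated peaks were matched by chance. Promoter peaks placed at 200 genes were assigned to all 200. Over the 21938 genes, the promoter test called 10 of 10 lists simulated with more marked members, 10 of 10 with fewer and 0 of 10 with no difference. The distal test called 10 of 10 lists with more peaks and 0 of 20 others. The McNemar test called 10 of 10 lists simulated with a replicate difference larger than any list here had. The 20 others were simulated with no member marked in 1 replicate only, so none could be called. This simulation therefore does not show the power or the error rate of the McNemar test on the lists here.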

Results

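H3K27ac peaks were mapped in the intestine of newborn mice, in 2 biological replicates labelled as pools of pups. Both carry the same donor identifier, so how far the pools are independent is not given in the sources used here. The list of replicate 1 held 126692 peaks on chromosomes 1 to 19, X and Y, covering 45.5 Mb, and that of replicate 2 held 88890 peaks covering 39.1 Mb. Median peak widths were 232 and 269 bp. The pooled list held 130724 peaks and the replicated list 48052, which covered 41.1 Mb or 1.51% of the genome with a median width of 600 bp. Peaks with a q of 0.01 or less made up 60.8% of the list of replicate 1, 74.2% of that of replicate 2 and 98.8% of the replicated list. The number of reads per library is not given in the sources used here. With a single tissue and age, the design allows a comparison of the replicates, of genomic locations and of gene groups within the tissue, and no comparison of conditions.

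The first question was how far the 2 pools marked the same elements. Almost all of the strongest peaks of each list had a partner of any strength in the other, and most of the weakest had none. Among replicate 1 peaks, 34.2% (43354 of 126692, 95% Wilson interval 34.0 to 34.5%) were found in replicate 2, against a mean of 2.08% for random placements, a 16.5-fold excess. Among replicate 2 peaks, 46.4% (41267 of 88890, 46.1 to 46.8%) were found in replicate 1, against 2.89% for random placements, a 16.1-fold excess. Both p-values were 0.0099, the smallest that 100 placements can give. By the authors' p within each list, 99.1% of the top decile of replicate 1 and 99.8% of that of replicate 2 were found. In the lowest decile the shares were 8.22% and 20.1%.

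Promoters were more frequent among the peaks that were found. In replicate 1, 38.8% of the peaks found in the other list lay at a promoter, against 15.2% of those not found. In replicate 2 the shares were 39.1% and 17.4%. When each list was restricted to its 20000 strongest peaks, 76.5% of those of replicate 1 and 73.9% of those of replicate 2 were found. Requiring an overlap of 50% of both peaks lowered the shares to 21.3% and 30.4%. Measured in covered bases, an alternative chosen after seeing the data, 49.5% of the bases of replicate 1 and 57.5% of those of replicate 2 lay in peaks of the other list.

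**Figure D1:**
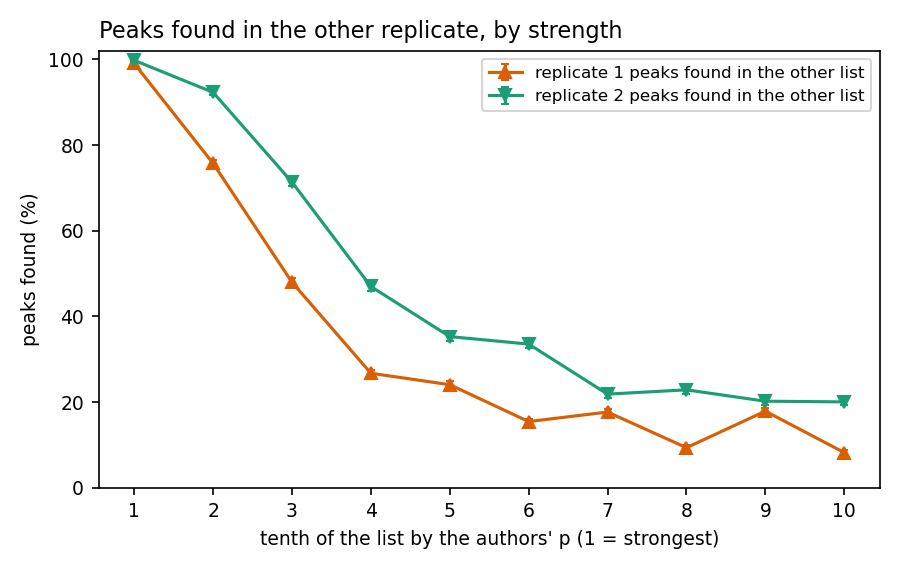
Share of peaks found in the other replicate (vertical axis, %) by decile of the list, ranked by the authors' p from strongest to weakest, with 95% Wilson intervals as bars. Orange triangles are replicate 1 peaks and green triangles replicate 2 peaks; both start at 99% or more and end at 8.22% and 20.1%.

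The second question was where in the genome the mark lay. Promoters of protein-coding genes held 16665 of the 48052 replicated peaks, 34.7% (34.3 to 35.1%), against 5.57% of randomly placed peaks. This was a 6.23-fold excess with a permutation p of 0.0099, the smallest that 100 placements can give. Introns held 37.7% of the peaks and exons 5.09%, against 34.7% and 2.71% by random placement. Intergenic sequence held 22.5%, against 57.0%. Promoter peaks had a median width of 831 bp and a median authors' fold of 7.25, whereas intronic peaks had medians of 519 bp and 4.53. Wide peaks overlap a promoter more easily, so part of the contrast in width may come from the rule of assignment. The excess at promoters was present in the list of each replicate taken alone, at 23.3% and 27.4% of peaks.

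The strongest replicated peaks lay mostly at promoters. The peak with the highest authors' fold, 69.7 (46.3 and 57.9 in replicates 1 and 2), covered the promoter of Erbin, which encodes a scaffold protein of the basolateral membrane of epithelial cells (chromosome 13, 103918571 to 103922115, mm10). Of the next 9, the peaks at Arrdc3, Rap1b, Sp3, Clk1, N4bp2, Kansl1 and Rnf19a lay at promoters, with folds of 57.5 to 60.7. Rap1b is a small GTPase, Sp3 a GC-box transcription factor, Clk1 a kinase of splicing factors and Kansl1 a subunit of a histone acetyltransferase complex. The other 2 were intergenic with respect to protein-coding genes. One, of 62.2-fold, lay 4653 bp from a start of Setd1b, a histone methyltransferase gene, over non-coding transcripts that include Gm26745 (chromosome 5, 123134451 to 123140630). The other, of 59.9-fold, lay 16764 bp from a start of the chromatin remodeller gene Chd2 and overlapped the non-coding gene 1810026B05Rik (chromosome 7, 73556670 to 73560520).

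At the level of genes, 11521 of 21938 protein-coding genes (52.5%) had a replicated promoter peak. The median authors' fold of the strongest promoter peak was 10.9, with quartiles of 6.71 and 17.5. In the replicates' own lists, 11558 genes were marked in both, 1163 in replicate 1 only, 633 in replicate 2 only and 8584 in neither. With both lists cut to the length of the shorter, 741 genes were marked in replicate 1 only and 929 in replicate 2 only. Which replicate had more genes of its own therefore depended on list length. The share rose with the CpG content around the gene's outermost 5′ end. In single deciles, 6.34% of genes in the decile of lowest CpG observed/expected ratio were marked, and 91.8% of those in the highest.

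The third question was which gene groups carried the mark. The lists of intestinal epithelium, enterocyte absorption, nuclear receptor, smooth muscle, gut mesenchyme, proliferation and housekeeping genes were marked more often than other genes. Among regulators and structural genes of the intestinal epithelium, 23 of 24 had a promoter peak (95.8%, 79.8 to 99.3%; exact adjusted p = 0.000135 in a two-sided Fisher's test, as for all lists here). The highest folds were at Epcam, an epithelial adhesion molecule (31.7 in the replicated list, 21.7 and 31.2 in those of replicates 1 and 2), and at Gata6, an endoderm transcription factor (24.4, 10.4 and 22.1). Foxa2, a forkhead factor of the endoderm, had no peak in any of these 3 lists. Chosen after their values were seen, Cdx1 and Cdx2, homeobox factors that specify intestinal identity, had folds of 19.9 (12.7 and 15.5 in the replicates) and 14.2.

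Genes of enterocyte absorption and digestion were marked at 21 of 23 promoters (91.3%, 73.2 to 97.6%; exact adjusted p = 0.000447). The leading members were Apoa1 and Apoc3, neighbouring apolipoprotein genes whose promoters lay under 1 peak of 21.0-fold (chromosome 9, 46223241 to 46237275). In the lists of replicates 1 and 2 the folds were 14.0 and 10.4 at Apoa1 and 12.7 and 11.8 at Apoc3. This peak of 14.0 kb was the widest in the replicated list. The members without a replicated peak were Sis, encoding the sucrase-isomaltase of the adult brush border, and Treh, encoding trehalase. Sis had no peak in either replicate, and Treh had one of 3.61-fold in replicate 1. Lct, encoding the lactase that digests milk sugar and chosen after its value was seen, had a replicated peak of 4.30-fold.

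Nuclear receptors and lipid regulators were marked at 14 of 17 promoters (exact adjusted p = 0.0214), led by Nr3c1, the glucocorticoid receptor gene (27.7-fold), and Rxra, the gene of a common partner of nuclear receptors (25.5-fold). Nr3c1 had no replicated peak at its outermost 5′ end. Fgf15, Slc10a2 and Fabp6, genes of ileal bile acid signalling and transport, had no replicated promoter peak. Genes of neonatal enterocyte uptake were marked at 9 of 11 promoters, which did not pass the threshold (exact adjusted p = 0.0921). Its leading members were the lysosomal genes Ctsb (25.2-fold) and Lamp1 (21.5-fold). Lrp2, encoding the endocytic receptor megalin, had no peak.

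Smooth muscle genes were marked at 16 of 19 promoters (exact adjusted p = 0.00896), with the highest folds at Tpm1, encoding a tropomyosin (15.6, or 9.18 at its outermost 5′ end), and Srf, encoding the serum response factor (13.7). Gut mesenchyme and fibroblast genes were marked at 17 of 20 promoters (exact adjusted p = 0.00595), led by the Hedgehog receptor gene Ptch1 (17.9) and the intermediate filament gene Vim (12.9). Proliferation genes were marked at 12 of 14 promoters (exact adjusted p = 0.0214), led by Birc5, an inhibitor of apoptosis (21.8), and Pcna, the sliding clamp of replication (12.7, with 6.59 and 11.7 in replicates 1 and 2). Random genes matched to this list on promoter CpG ratio were marked at 78.6%, and against them the list did not pass. All 18 housekeeping genes were marked (82.4 to 100%; exact adjusted p = 0.000149), with folds of 55.6 at Ywhaz and 48.9 at Actb. Ywhaz had 31.95 and 47.6 in replicates 1 and 2, and 3.96 at its outermost 5′ end, so the strong peak lay at another of its starts.

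Gene lists of other epithelial cell types were marked less often or did not differ from other genes. Of 18 enteroendocrine genes, 1 had a replicated promoter peak (5.56%, 0.988 to 25.8%; exact adjusted p = 0.000283), against 3 and 4 in the lists of replicates 1 and 2 alone, where the call held. The gene with a replicated peak was Sct, encoding the hormone secretin (17.5-fold, with 10.2 and 13.8 in replicates 1 and 2), and its peak also covered the start of Cdhr5, a neighbouring gene of the brush border. Neurog3 and Neurod1, transcription factors of the lineage, had no peak in any list. Of 12 Paneth and tuft cell genes, 1 was marked, the stress-response gene Nupr1 (4.41-fold; exact adjusted p = 0.00497). In the lists of replicates 1 and 2 alone, 4 and 3 were marked, which did not pass (exact adjusted p = 0.187 and 0.0556). Goblet cell genes did not pass the threshold, at 4 of 12 (exact adjusted p = 0.303). Muc13, encoding a membrane mucin, and the goblet cell factor gene Spdef had folds of 9.22 and 5.91 (Spdef 5.87 and 2.91 in replicates 1 and 2, and 3.22 at its outermost 5′ end), and the secreted products Muc2 and Tff3 had no replicated peak. Crypt and stem cell genes did not pass either, at 10 of 15 (exact adjusted p = 0.348). The Wnt target Axin2 had a fold of 29.6 and the growth factor signalling inhibitor Lrig1 of 14.0, whereas the stem cell markers Lgr5, Ascl2, Olfm4 and Smoc2 had no replicated peak. In the lists of replicates 1 and 2 alone, 9 and 12 of the 15 were marked. Some members without a replicated peak therefore had a promoter peak in replicate 2.

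In the replicated list, enteric nerve, immune and mesothelium genes were also marked less often, but the first did not pass in either replicate's own list and the last not in that of replicate 1. The endothelial, Cajal cell and erythroid lists did not pass the threshold. Of 20 genes of enteric neurons and glia, 5 were marked (exact adjusted p = 0.0316), with the highest folds at Ednrb, encoding the endothelin receptor of migrating neural crest cells (6.71), and at Hand2, a factor of enteric neurons (5.91). In the lists of replicates 1 and 2 alone, 9 and 7 were marked (exact adjusted p = 0.32 and 0.0857). Of 18 immune cell genes, 2 were marked (exact adjusted p = 0.00146), the macrophage gene Cd68 (4.07) and Fcer1g (3.76), whose peak also covered a start of Ndufs2. None of 7 mesothelium genes was marked (exact adjusted p = 0.00896), against 2 in the list of replicate 1 alone (exact adjusted p = 0.187). Endothelial genes were marked at 8 of 17 promoters (exact adjusted p = 0.809), led by Eng (12.7, or 7.80 at its outermost 5′ end) and Pecam1 (6.16, with 4.07 and 3.46 in replicates 1 and 2). Pecam1 had no replicated peak at its outermost 5′ end. Genes of interstitial cells of Cajal, the pacemakers of gut movement, were marked at 2 of 7, Etv1 (12.2, with 7.33 and 9.16 in replicates 1 and 2) and Gja1 (4.16; exact adjusted p = 0.313). Erythroid genes were marked at 4 of 11 (exact adjusted p = 0.398), led by the red cell regulators Klf1 (8.60, with 4.99 and 8.74 in replicates 1 and 2) and Tal1 (4.35). The globin genes Hba-a1, Hbb-bs and Hbb-bt had no peak, but these have near-identical copies, so the absence of a call there is uncertain.

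Genes of other organs and of the germline were marked less often in 7 of 8 lists. No stomach gene (0 of 14, exact adjusted p = 0.000275), lung epithelium gene (0 of 10, exact adjusted p = 0.00163) or skeletal muscle gene (0 of 12, exact adjusted p = 0.000458) had a replicated promoter peak. In the list of replicate 1 alone, 1 lung epithelium gene and 2 skeletal muscle genes were marked, and in that of replicate 2 none. Pancreatic acinar genes were marked at 2 of 21 (exact adjusted p = 0.000401), Cela1 (5.50) and Cpa2 (3.76). Neither had a replicated peak at its outermost 5′ end. In the lists of replicates 1 and 2 alone, 3 and 4 acinar genes were marked. Cardiac genes were marked at 1 of 13 (exact adjusted p = 0.00277), Tnnt2 (4.16, with 4.93 in replicate 2 and no promoter peak in replicate 1). In the lists of replicates 1 and 2 alone, 3 and 2 cardiac genes were marked, none of them in both. Forebrain genes were marked at 2 of 17 (exact adjusted p = 0.00223), the transcription factor genes Bcl11b (10.3) and Satb2 (9.94, with 6.23 and 9.58 in replicates 1 and 2). Satb2 had no replicated peak at its outermost 5′ end. Germline genes were marked at 2 of 15 (exact adjusted p = 0.00595), Dazl (5.86, with 6.78 and 3.46 in replicates 1 and 2) and Brdt (4.83, but no replicated peak at its outermost 5′ end). Hepatocyte genes did not pass the threshold, at 7 of 17 (exact adjusted p = 0.485). The highest folds were at the nuclear receptor gene Nr1i3 (17.2, with 10.8 and 16.2 in replicates 1 and 2) and at Apoh (11.6), whose peak also covered a start of Prkca. Chosen after their values were seen, the other marked members were Ttr (8.06, with 4.28 and 8.74 in replicates 1 and 2), G6pc (6.18), Trf (5.10), F2 (4.56) and Fga (4.03). The Trf peak also covered a start of Gm20425. Alb, Afp, Ahsg and Fgb had no peak in any of these lists.

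Homeobox genes of the Hox clusters were examined by paralogue group. None of 12 genes of groups 10 to 13, which pattern the hindmost body, had a replicated promoter peak (0 to 24.2%; exact adjusted p = 0.000458). In the lists of replicates 1 and 2 alone, 3 and 2 were marked (exact adjusted p = 0.0527 and 0.0123). Groups 1 to 9 were marked at 19 of 27 (70.4%, 51.5 to 84.1%), which was not past the threshold against other genes (exact adjusted p = 0.104). Their highest folds were 18.4 at Hoxb4 (11.4 and 18.1 in replicates 1 and 2) and 11.8 at Hoxa4. The 2 Hox lists were not tested against each other.

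In all, 7 lists were marked more often and 13 less often than other genes. Against random genes matched on CpG content at the outermost 5′ end, an inexact match for genes marked at another start, 6 and 8 lists passed. The calls that ended there were those of proliferation, Paneth and tuft, immune, mesothelium, pancreatic acinar and skeletal muscle genes, whose highest adjusted p over all alternatives were 1, 0.225, 0.389, 0.187, 0.223 and 0.0560 and whose lowest were 0.00237, 0.00055, 0.000808, 0.00735, 1.53e-05 and 0.000413. In the list of either replicate alone, the Paneth and tuft call and the enteric neuron and glia call (adjusted p from 0.0094 to 0.32 over its alternatives) ended, the latter also with a window of 2500 bp. Without replicate 2, those of mesothelium and Hox groups 10 to 13 (0.000463 to 0.0527) ended too. With only the outermost 5′ end of each gene, the calls of nuclear receptor and lipid genes (0.0049 to 0.507) and smooth muscle genes (0.0012 to 0.0548) ended.

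**Figure D2:**
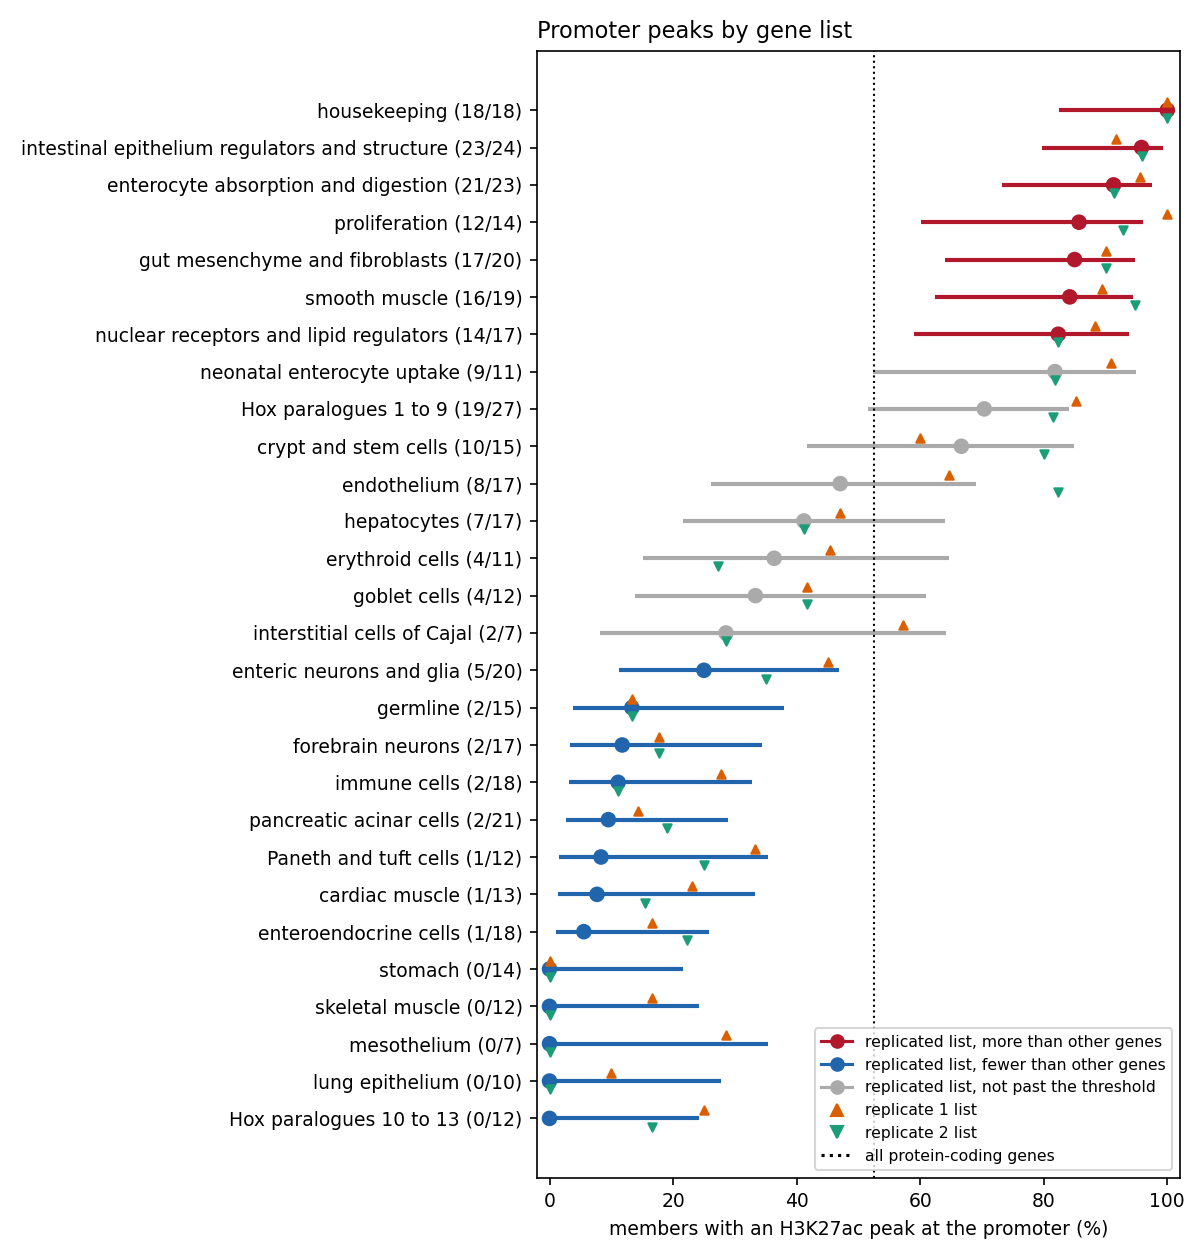
Share of each gene list's members with an H3K27ac promoter peak (horizontal axis, %), with 95% Wilson intervals as bars; circles are the replicated list and triangles the list of replicate 1 (orange) or replicate 2 (green), and the dotted line is the 52.5% of all protein-coding genes. Red lists were marked more often than other genes, blue lists less often and grey lists did not pass an adjusted p of 0.05.

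The fourth question was whether the pools differed in a cell type or a neighbouring organ. No difference between the pools was detected, but the test had little reach. The exact McNemar test gave 0 of 28 lists at an adjusted p under 0.05 and also 0 at an unadjusted p under 0.05. The smallest unadjusted p was 0.25, for crypt and stem cell genes (9 members in replicate 1, 12 in replicate 2) and immune genes (5 and 2). Endothelial genes were marked at 11 and 14 promoters, of which 1 and 4 were marked in that replicate only. No list had more than 5 members marked in 1 replicate only, and with 5 the smallest two-sided exact p is 0.0625, so no list could have passed.

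The fifth question was which genes lay near distal peaks, where enhancers are found. Of the replicated peaks, 31387 were distal, and the median gene had 1 of them within 50 kb. In 6 of 28 lists genes had more of them than random genes. Regulators and structural genes of the epithelium had a median of 11.5 distal peaks (adjusted p = 0.0014 in a two-sided permutation test against random lists), and Cdh1, the gene of epithelial cadherin, had 27. Neonatal enterocyte uptake genes had a median of 10 (adjusted permutation p = 0.00224), nuclear receptor and lipid genes 9 and enterocyte genes 7 (adjusted permutation p = 0.0014 for both). Smooth muscle genes had a median of 7 (adjusted permutation p = 0.0028). Hox groups 1 to 9 had a median of 12 (adjusted permutation p = 0.0014), but genes of a cluster count the same peaks, so this list holds few independent values. Goblet, crypt and stem, Paneth and tuft, and enteroendocrine genes, with medians of 2.5, 2, 1.5 and 0, did not pass the threshold (adjusted permutation p of 0.786 or more). Housekeeping genes had a median of 5, which also did not pass the threshold (adjusted permutation p = 0.0536).

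No list had fewer distal peaks than random lists at an adjusted p under 0.05. A median gene had 1 distal peak, so a lower value could hardly be detected. The smooth muscle call ended with windows of 20 and 100 kb and without replicate 2 (adjusted p from 0.000933 to 0.213 over all alternatives). The housekeeping list passed in either replicate's list alone, at a q of 0.01 or less and at 100 kb (0.00747 to 0.168). Proliferation genes, with a median of 3 at 50 kb, passed at 20 kb only (0.0308 to 0.825).

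**Figure D3:**
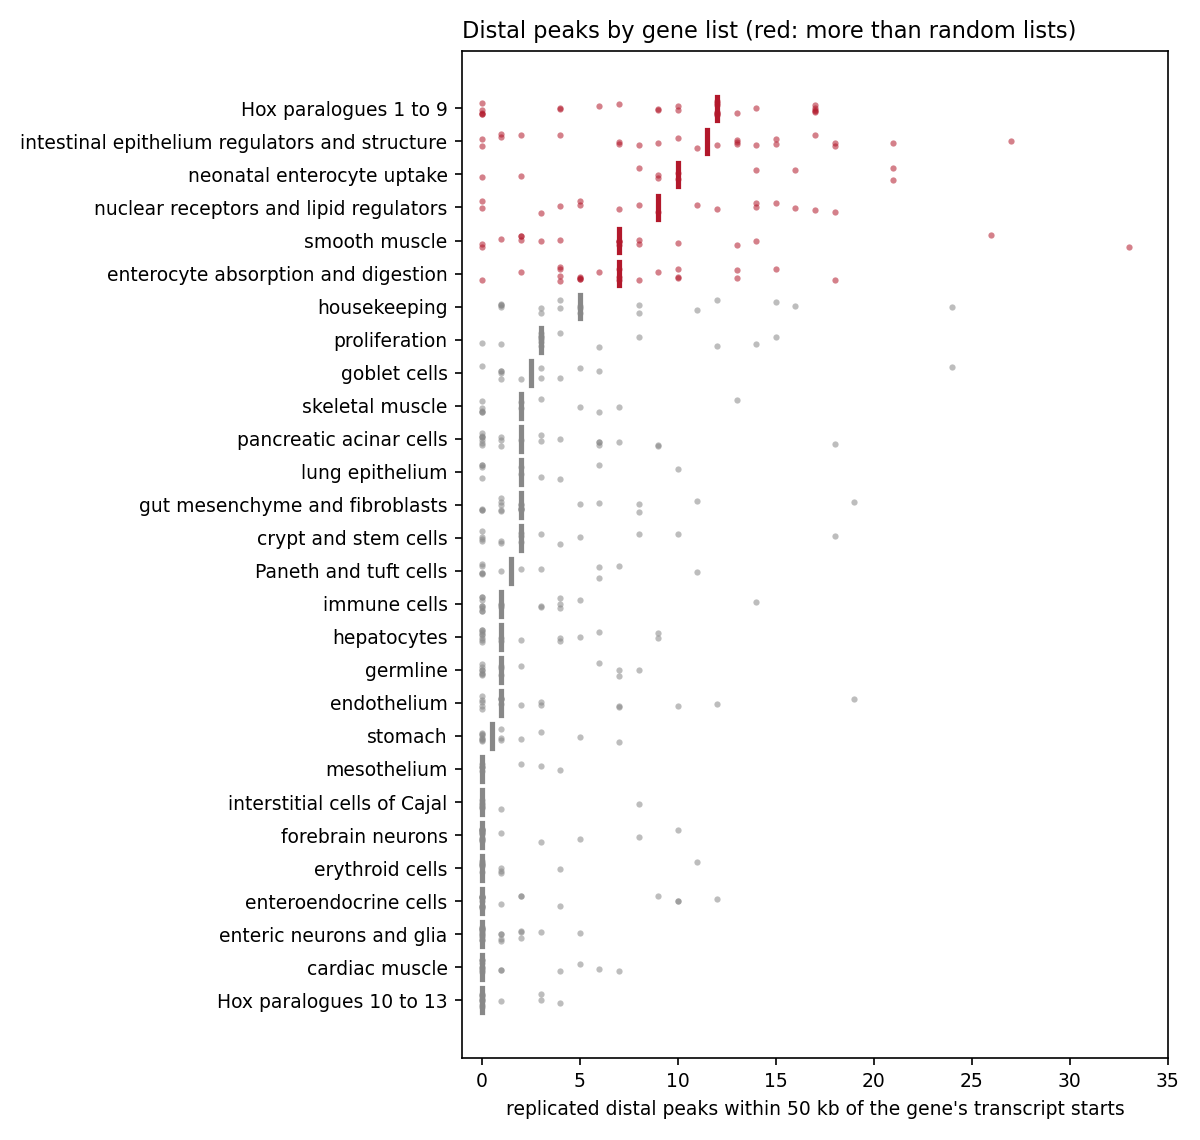
Number of replicated distal peaks within 50 kb of each gene (horizontal axis), by gene list; points are genes and thick bars list medians. The 6 lists in red had more than random lists at an adjusted p under 0.05, with medians of 7 to 12.

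The last question was where distal peaks were most concentrated. Joining 26907 peaks gave 11504 stitched regions, of which 5992 held a single peak and 256 held 10 or more. The leading region covered 36.4 kb with 39 peaks and lay within Cmip (chromosome 8, 117261209 to 117388256), which encodes an adaptor protein of T cell signalling. The next, with 32.6 kb covered, had Il17b as its nearest protein-coding gene (chromosome 18, 61609184 to 61681864). It held no protein-coding gene and overlapped the non-coding genes Bvht, Mir145a, Mir143 and Carmn, whose microRNAs are abundant in smooth muscle. The region that followed, with 31.4 kb covered and Frmd8 nearest (chromosome 19, 5793832 to 5853457), overlapped the nuclear long non-coding RNA genes Malat1 and Neat1.

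Epithelial genes were also among the 10 leading regions. The region at Cdh1 covered 24.4 kb (chromosome 8, 106563443 to 106642236), spanning the promoter-distal sequence upstream and the first part of the gene. The region at Hnf4a, a nuclear receptor that maintains enterocyte identity, covered 23.5 kb (chromosome 2, 163530093 to 163597033). It ran from inside the gene (163506808 to 163572910) to the sequence beyond its 3′ end, and a transcript start of Hnf4a lay 13.5 kb from the region's centre. Map7, encoding a microtubule-binding protein of epithelia, covered 27.6 kb. Ankrd11, Mertk, Igf2r and Zmiz1 were nearest to the remaining regions, with 24.5, 23.9, 23.6 and 23.6 kb. In each of the 10 regions both replicates' lists covered at least 20.9 kb. The ranking depended on how regions were built. Of the 10 leading regions, 3 were among the leading 10 with a joining distance of 5 kb, 3 when ranked by fold times length and 2 without the promoter exclusion.

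**Figure D4:**
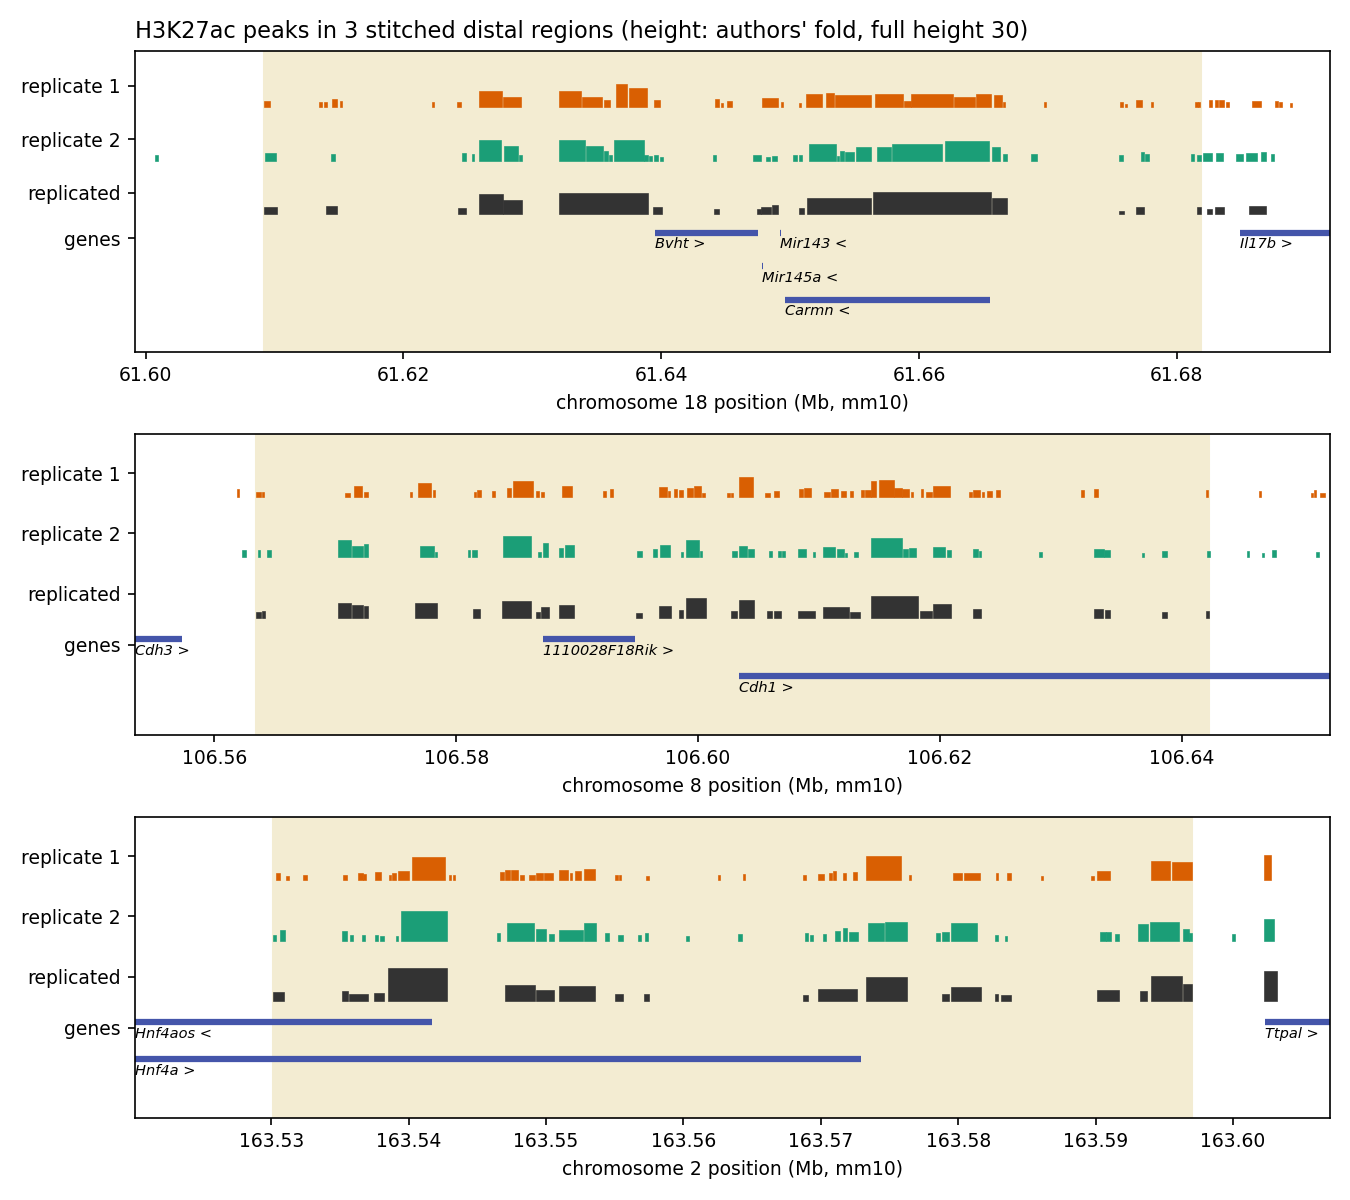
H3K27ac peaks in 3 of the 10 leading stitched distal regions (shaded), near Il17b, Cdh1 and Hnf4a, by position (Mb, mm10). Boxes are peaks of replicate 1 (orange), replicate 2 (green) and the replicated list (black), with heights proportional to the authors' fold within each list; blue bars are annotated genes, without predicted genes named Gm, with > or < for the strand. The regions have 32.6, 24.4 and 23.5 kb covered by replicated peaks.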

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

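The pooled list held 82672 peaks on chromosomes 1 to 19, X and Y that are outside the replicated list. They entered the matching of pooled peaks to both replicates' lists but no other comparison above. They were flagged because a signal lies in data that the other comparisons do not use. Their median width was 224 bp and their median authors' fold 3.04, and 16.1% of them (15.9 to 16.4%, Wilson) lay at a promoter. A further 8 rows of the replicated list lay on unplaced sequences, were flagged for the same reason and were not analysed here.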

How the results depend on the processing

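The share of covered bases was chosen after seeing the data, and all other alternatives were planned. The 2 overlap shares ranged from 21.3 to 76.5% and from 30.4 to 73.9% over their alternatives, each with the smallest p that random placements can give. The promoter share ranged from 30.8 to 44.0% over windows and thresholds and was 23.3 and 27.4% in the lists of replicates 1 and 2. Genes with a promoter peak numbered 10670 to 12721. Lists marked more often numbered 5 to 9 and lists with more distal peaks 6 or 7. Lists marked less often numbered 9 without replicate 2 and 11 without replicate 1, and 12 or 13 under the other thresholds and windows. Matching the background on promoter CpG ratio left 8 of 13. The cause of the ended calls was not tested. Taken alone, the list of replicate 1 added calls of more frequent marking for neonatal enterocyte uptake and Hox groups 1 to 9, and that of replicate 2 added endothelium and Hox groups 1 to 9. The exact McNemar test called no list under any of the 3 alternatives, where the smallest unadjusted p was 0.125 and no list had more than 6 members marked in 1 replicate only. Stitched regions numbered 11383 to 16637. Of 249 alternative values of named promoter peaks, 59 moved by more than 1 SD of the replicates and 54 of these came from a single replicate's list. The fold of 16 of 43 named promoter peaks moved by more than 1.5 times under some setting. No paired analysis was possible because the series holds 1 group. Read depth is unknown, so absent and undetected peaks cannot be separated.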

Other observations

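The 9 gene lists of the next 2 paragraphs were chosen after the results above were seen but before their own values were. The genes named from them were chosen after their values were seen. Tests were two-sided Fisher's exact tests, adjusted over the 9 lists. Structural genes of the brush border, the microvillus surface of enterocytes, had a promoter peak at 16 of 16 (exact adjusted p = 0.000174), of which Vil1 was also in a list above. Among them, Misp and Eps8l2, which encode actin regulators, had folds of 30.3 and 27.9 (Misp 16.6 and 23.2 in replicates 1 and 2), and Ezr, the ezrin gene, had 34 distal peaks within 50 kb. Genes of tight and adherens junctions were marked at 15 of 15 (exact adjusted p = 0.000174), with Ctnna1 at 41.2-fold (39.0 and 19.9 in replicates 1 and 2) and Ctnnd1 at 33.6-fold. Lysosome and autophagy genes were marked at 18 of 18 (exact adjusted p = 9.6e-05) and immediate early genes at 15 of 15 (exact adjusted p = 0.000174). Among these, Gba and Nr4a1 had no promoter peak in the list of replicate 1. Zfp36, a regulator of mRNA decay, had a fold of 42.2 in a peak of 11.1 kb, and the stress-responsive autophagy receptor gene Sqstm1 of 39.9. Clock genes were marked at 13 of 14 (exact adjusted p = 0.00241), of which Ciart had no promoter peak in the list of replicate 2.

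Ligands, receptors, effectors and inhibitors of 3 sets of signalling pathways were also examined, leaving out genes of the lists fixed earlier. Hedgehog and BMP genes were marked at 18 of 20 (exact adjusted p = 0.000951). The ligand gene Ihh had a fold of 19.9 (13.1 and 12.4 in replicates 1 and 2), and Shh had no peak. Notch genes were marked at 13 of 14 (exact adjusted p = 0.00241), with Jag1 at 37.6-fold and Hes1 at 30.7-fold. Wnt genes were marked at 8 of 20 (exact adjusted p = 0.273), less often than the 80.0% of random genes of matched CpG content (adjusted permutation p = 0.0006). The receptor and effector genes Lrp6, Apc, Tcf7l2 and Lrp5 had folds of 31.7, 26.7, 22.3 and 17.7, and Lef1, another effector, had no peak. Of the ligand genes in this list, Wnt11 had a replicated peak of 4.83-fold. Wnt2b, Wnt4 and Wnt5b had a peak in 1 replicate only, and Wnt3, Wnt6 and Wnt9b had none. The agonist genes Rspo1, Rspo2 and Rspo3 and the inhibitor genes Sfrp1 and Dkk1 had none. The share of 8 of 20 does not describe the whole pathway. Among the genes left out were the ligand gene Wnt5a (6.11-fold) and Axin2, Rnf43 and Znrf3 (29.6, 5.63 and 6.58), but also Lgr5, without a replicated peak. Antimicrobial and Reg genes were marked at 1 of 13 (exact adjusted p = 0.00178), Lypd8 at 6.18-fold, but matched genes were marked at 15.4% (adjusted permutation p = 0.459). Against matched genes, the Hedgehog and BMP list, the clock list and the Notch list also did not pass (adjusted permutation p = 0.202, 0.214 and 0.0531), the last within the random error of the draws around the threshold.

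Of the tests below, those on the strength of peaks, on the makeup of the pools and on carried-over liver were chosen after the result was seen. No group of the design offers a biological explanation for any of the 3 patterns, so none was tested as a group difference.

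Fewer than 50% of each replicate's peaks were found in the other under the main overlap rule, but 53.9% of replicate 2 peaks were found when 1 shared base was enough, and 76.5 and 73.9% when both lists were cut to their top 20000. Splitting of one element into several narrow peaks could account for part of the replicate 1 peaks not found, but not for the majority of them. Of these, 37.3% (36.9 to 37.6%) lay within 1 kb of a replicate 2 peak, against 7.1% by random placement. The replicate 2 peaks not found were not tested in this way, so for them splitting stays open. A different cell makeup of the 2 pools stays open, because no gene list had more than 5 members marked in 1 replicate only in the main setting and 6 under the alternatives. With lists of equal length endothelial genes had 1 and 5 (unadjusted p = 0.219, exact McNemar test), and with 6 the smallest p is 0.0312, which cannot pass over 28 lists. Weak peaks near the calling threshold are a candidate explanation, as the top and lowest deciles of each list differed by at least 79.7 percentage points in the share found.

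Some members of the lists of other organs and of the germline had a promoter peak, 14 of 119 in 8 lists, and 7 of the 14 were in the hepatocyte list. Liver tissue carried over with the intestine stays open, as the hepatocyte list was marked at 41.2% (21.6 to 64.0%), against 29.4% of random genes of matched CpG content (adjusted permutation p = 0.405), with peaks at Ttr and Trf but none at Alb, Afp, Ahsg and Fgb, which were singled out after their values were seen. A promoter shared with a neighbouring gene could explain a few. Such a peak was seen at 14.3% of the 14 members (4.0 to 39.9%), namely Apoh and Trf, against 24.7% of other marked genes (p = 0.539, two-sided Fisher's exact test), so this stays open. Expression of these genes in intestinal cells was not tested.

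The X chromosome held few peaks, 0.66 per protein-coding gene against 2.28 on the autosomes, and 289 of its 948 genes (30.5%, 27.6 to 33.5%) were marked against 54.0% of autosomal genes. X-linked genes had a mean of 0.5 distal peaks within 50 kb, against 3.12 for autosomal genes. CpG content at the outermost 5′ end of X-linked genes is argued against as the whole cause, since 44.1% of matched autosomal genes were marked. A candidate explanation is that cells hold fewer active copies of the X than of an autosome. Marked X-linked genes had a median fold 0.774 times that of matched marked autosomal genes (95% bootstrap interval 0.674 to 0.89). This ratio covers only genes with a called promoter peak, and no further explanation of the few peaks was tested. The pools were of mixed sex, and how far the control library removes copy number from the fold is unknown, so X inactivation and copy number cannot be separated here.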
